A study of Rattus norvegicus with 26 samples.

How the data were processed

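RNA from primary neuronal, astrocytic, oligodendrocytic and microglial cultures of newborn rat cortex, and from mixtures of it, was hybridised to 26 Affymetrix arrays. The deposited values are log2 expression values made by the authors with Robust Multi-array Average (RMA) in the affy package, per the labels, with background correction, quantile normalization and summarisation into probe sets. The labels give no version of RMA or affy. The table held 31099 probe sets with values between 2.57 and 14.36, and these were used as they stand. Control probe sets (57) were left out, and 31042 were tested with no filter on low values. Of these, 20826 carried 1 gene symbol, 436 several and 9780 none, and 14217 genes were each represented by the probe set with the highest mean over the 26 arrays. Gene identifiers were matched to the GRCr8 annotation for 20758 probe sets, and 0 symbols changed.

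Groups followed the titles and cell types: 4 replicates of each of 4 cultures and 2 replicates of each of 5 mixtures. Microglial replicate 4, whose description reads as a mixture, was kept as a culture, and the comparisons were repeated without it. Cultures and mixtures were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in separate fits with 1 mean per culture or mixture. Each culture was compared with the mean of the other 3 and with each other culture. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 31042 probe sets of a contrast and a log2 difference of at least 1, and counted as higher than each other culture when it passed all 3 pairwise contrasts. For the mixtures, the slope on the neuronal RNA fraction (intercept and slope over 6 arrays), NAO against NA2 and NAOM against NAO were tested with no minimum difference. Folds are 2 to the power of the log2 difference.

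There were 32 gene lists (11 of cell type markers and 21 of functions, 412 genes of which 359 were measured), tested in 4 culture contrasts with camera (preset correlation 0.01, adjusted over the 128 tests), and again with a correlation estimated from the data. A second meningeal list of 16 genes, 14 of them measured, was written for 1 test after the cultures had been seen. Expected mixture values were the fraction-weighted sums of the linear values of the stated parents. RNA fractions were estimated by non-negative least squares on culture means over the neuron, astrocyte, oligodendrocyte and microglia lists and rescaled to a sum of 1. Expression per population was estimated by least squares on the stated fractions.

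Comparisons, thresholds, the 32 lists and the rule for named genes were chosen before the data were examined, as were the alternatives except those stated to have been chosen later. The rule named, per culture, the 15 genes with the largest smallest difference from any other culture among those called against each of them with no overlap of arrays; the 8 largest slopes each way; the 8 largest changes each way for the other mixture contrasts that went the same way in both replicates; and members of the lists. Postn was named outside the rule, after its values were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0 were also used. The calls were tested on simulated data with 100 changed probe sets at each of 2 sizes of change. The neuron contrast recovered 92% of log2 changes of 1.5 and 99% of 3, with 4 calls among 30842 unchanged probe sets. The slope recovered 36% of slopes of 2 and 82% of 5, with 4 calls, and NAO against NA2 76% of changes of 1.5 and 93% of 3, with 7 calls. The simulated data held fewer changed probe sets than the neuron contrast, slope and NAO against NA2 called, and noise independent between arrays. These shares therefore do not carry over to the real comparisons.

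Whether replicate numbers paired the arrays was checked on residuals. Numbers did not pair the cultures: r between same-numbered residuals of different cultures lay between -0.107 and 0.178 over 24 pairs, with 5 above 0.1. The numbers paired the mixtures, which the labels tie to shared parents, with r from 0.381 to 0.873, and blocked values are given beside the mixture counts. Alternatives were a replicate block, median centring, quantile normalization of cultures or mixtures alone, removal of the dimmest 25% of probe sets, other fold minima, a trended and robust variance, array weights, fits on the compared groups alone and leaving out each replicate. For the mixtures they also included other parent profiles, log2 mixing, other reference arrays and other probe sets. Probe sets without a symbol were tested but not named, and sequences of the probes were not analysed here.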

Results

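Gene expression was measured on 26 Affymetrix oligonucleotide arrays that carried biotin-labelled RNA from cortical cells of newborn rats. Primary neuronal, astrocytic, oligodendrocytic and microglial cultures, grown from the cerebral cortex, were each represented by 4 biological replicates. The labels say no more than that about how independent the replicate cultures were. The other 10 arrays carried mixtures of RNA from these cultures, with 2 replicates of each of 5 mixing proportions. NA1, NA2 and NA3 held neuronal RNA at fractions of 0.25, 0.5 and 0.75, with astrocytic RNA making up the rest. NAO held 0.5 neuronal, 0.25 astrocytic and 0.25 oligodendrocytic RNA, and NAOM held 0.5 neuronal, 0.2 astrocytic, 0.2 oligodendrocytic and 0.1 microglial RNA. Replicate 1 of every mixture was made from neuron replicate 1 and astrocyte replicate 1, and replicate 2 from neuron replicate 2 and astrocyte replicate 4.

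The median log2 expression per array lay between 5.25 and 5.31 in the cultures and between 5.33 and 5.41 in the mixtures. Across genes within pairs of arrays, where genes are not independent replicates, Pearson's r between replicate cultures ranged from 0.974 to 0.995 for neurons, 0.942 to 0.995 for astrocytes, 0.967 to 0.985 for oligodendrocytes and 0.977 to 0.989 for microglia. Neuronal replicates 1 and 2 (r 0.992) and neuronal replicates 3 and 4 (r 0.995) were closer than arrays taken across these pairs (r 0.974 to 0.981). The fits nevertheless treat the 4 neuronal arrays as independent. Oligodendrocyte and microglial arrays resembled each other more (r 0.904 to 0.955) than neuronal and microglial arrays did (r 0.736 to 0.808). The number of arrays limits the precision of every value. Differences are given on the log2 scale with their standard error (n = 4 arrays per culture), as one culture minus the mean of the other 3, and levels as mean ± SD. Where the lower of the levels compared lay below the median of every array, background compresses the difference, so such a fold or log2 difference is a lower bound and ranks among such genes carry little weight. That point was added after the values were seen. The bound concerns background only and leaves out the standard error. The mean of the other 3 cultures is a mean of log2 values, and a single culture in it can lie well above the floor. The fold over that culture is then smaller than the fold given.

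The first question was which transcripts marked each population, and the neuronal cultures come first. Snap25, a membrane fusion protein of synaptic vesicles, was at least 231-fold higher in neuronal cultures than in the mean of the others (7.85 ± 0.36), at 12.59 ± 0.04 against 3.61 ± 0.26 in astrocyte cultures. The calcium sensor Vsnl1 was 170-fold higher (7.41 ± 0.36), the brain phospholipid phosphatase-related protein Plppr4 155-fold (7.27 ± 0.28) and the long noncoding RNA Meg3 145-fold (7.18 ± 0.14). The interneuron peptides vasoactive intestinal peptide, Vip (135-fold, 7.08 ± 0.18), and somatostatin, Sst (91.8-fold, 6.52 ± 0.36), were among the 15 genes that stood furthest above every other culture, as were the GABA-A receptor subunit Gabrb2 (116-fold, 6.85 ± 0.17) and complexin, Cplx1 (122-fold, 6.93 ± 0.22). The same group held Tmem130 (135-fold, 7.08 ± 0.36), Elmod1 (123-fold, 6.94 ± 0.42), Arpp21 (90.7-fold, 6.5 ± 0.26), Mpped1 (80.4-fold, 6.33 ± 0.26), the neurofilament light chain Nefl (79.8-fold, 6.32 ± 0.21), the regulator of G protein signalling Rgs4 (72.9-fold, 6.19 ± 0.19) and the neuropeptide Y receptor Npy1r (66.3-fold, 6.05 ± 0.15). The other cultures averaged below the median of every array for all 15, so these folds are lower bounds. For all 15 genes the limma adjusted p lay between 9.82e-15 and 1.55e-09. The rule picked only genes whose lowest neuronal array exceeded the highest array of every other culture, so this separation adds no evidence. In all, 3675 probe sets were higher and 3309 lower in neuronal cultures among 31042 tested, and 2326 probe sets (1265 genes) were higher than in each of the other cultures.

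Gene groups of neuronal function were higher in neuronal cultures. All 16 genes of the neuron list passed the threshold (16 adjusted over the list alone, camera adjusted p = 3.92e-10, and adjusted p = 0.0224 with an estimated correlation). These included Celf4 (5.71 ± 0.31), the adhesion molecule L1cam (5.18 ± 0.23) and the microtubule protein Map2 (2.10 ± 0.31). Of the genes for synaptic vesicles and release, 11 of 13 were higher (11 adjusted over the list alone, camera adjusted p = 2.41e-08, and adjusted p = 0.0224 with an estimated correlation). These included the syntaxin Stx1a (5.01 ± 0.20), the vesicle GTPase Rab3a (4.36 ± 0.13) and synaptophysin, Syp (4.08 ± 0.24). Glutamate receptor genes were higher for 11 of 13 (11 adjusted over the list alone, camera adjusted p = 1.33e-06, and adjusted p = 0.04 with an estimated correlation). These included the obligate NMDA receptor subunit Grin1 (3.94 ± 0.12) and the metabotropic receptor Grm5 (3.03 ± 0.52). GABA-A receptor subunits were higher for 7 of 8 (7 adjusted over the list alone, camera adjusted p = 1.91e-05, and adjusted p = 0.04 with an estimated correlation), with Gabra5 (5.66 ± 0.13) as an example and Gabrg1 (-0.14 ± 0.40) as the exception. Voltage-gated channels were higher for 7 of 10 (7 adjusted over the list alone), among them the sodium channels Scn2a (4.80 ± 0.15) and Scn3a (4.28 ± 0.23). That list had camera adjusted p = 0.000144, and adjusted p = 0.0583 with an estimated correlation.

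Transcripts of both inhibitory and excitatory neurons were present. In the interneuron list 10 of 11 genes were higher (10 adjusted over the list alone, camera adjusted p = 1.04e-06, and adjusted p = 0.0555 with an estimated correlation). These included the GABA-synthesising enzyme Gad1 (6.72 ± 0.59), the vesicular GABA transporter Slc32a1 (6.08 ± 0.23) and cholecystokinin, Cck (5.76 ± 0.21). In the excitatory cortical list 8 of 10 were higher (8 adjusted over the list alone, camera adjusted p = 3.78e-06, and adjusted p = 0.0992 with an estimated correlation). These included the glutamate transporters Slc17a6 (4.39 ± 0.18) and Slc17a7 (3.77 ± 0.24) and the transcription factor Bcl11b (4.83 ± 0.18). The mean of the excitatory list was 8.23 and 8.08 in neuron replicates 1 and 2 against 7.11 and 7.28 in replicates 3 and 4, and that of the interneuron list was 9.02 and 8.96 against 9.74 and 9.76.

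Cholesterol synthesis genes were also higher in neuronal cultures, 12 of 14 of them past the threshold (12 adjusted over the list alone, camera adjusted p = 1.39e-06, and adjusted p = 0.238 with an estimated correlation). These included the isopentenyl isomerase Idi1 (2.21 ± 0.28) and Hsd17b7 (2.78 ± 0.19). The list averaged 10.08 in neuronal and 10.20 in oligodendrocyte cultures, against 7.61 in astrocyte and 7.63 in microglial ones. It therefore did not set neurons apart from oligodendrocytes. Cell division genes were lower for 15 of 16 (15 adjusted over the list alone, camera adjusted p = 1.98e-08, and adjusted p = 0.144 with an estimated correlation). These included the mitotic kinase Cdk1 (-4.95 ± 0.12) and the topoisomerase Top2a (-4.42 ± 0.16). All 12 lysosome genes were lower (12 adjusted over the list alone, camera adjusted p = 1.35e-06, and adjusted p = 0.102 with an estimated correlation). These included cathepsin Z, Ctsz (-5.21 ± 0.30). Markers of other cells varied between the neuronal arrays: the mean of the astrocyte list was 8.23 ± 0.97 against 9.98 ± 0.47 in astrocyte cultures, and it ran from 7.05 in neuron replicate 1 to 9.12 in neuron replicate 3. Gfap, the intermediate filament of astrocytes, stood at 11.65 ± 0.99 and the water channel Aqp4 at 9.24 ± 1.46 in neuronal cultures. The microglia list had 17 of 18 genes lower (17 adjusted over the list alone, camera adjusted p = 4.61e-07, and adjusted p = 0.208 with an estimated correlation), and its mean was 4.68 ± 0.10.

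**Figure D1:**
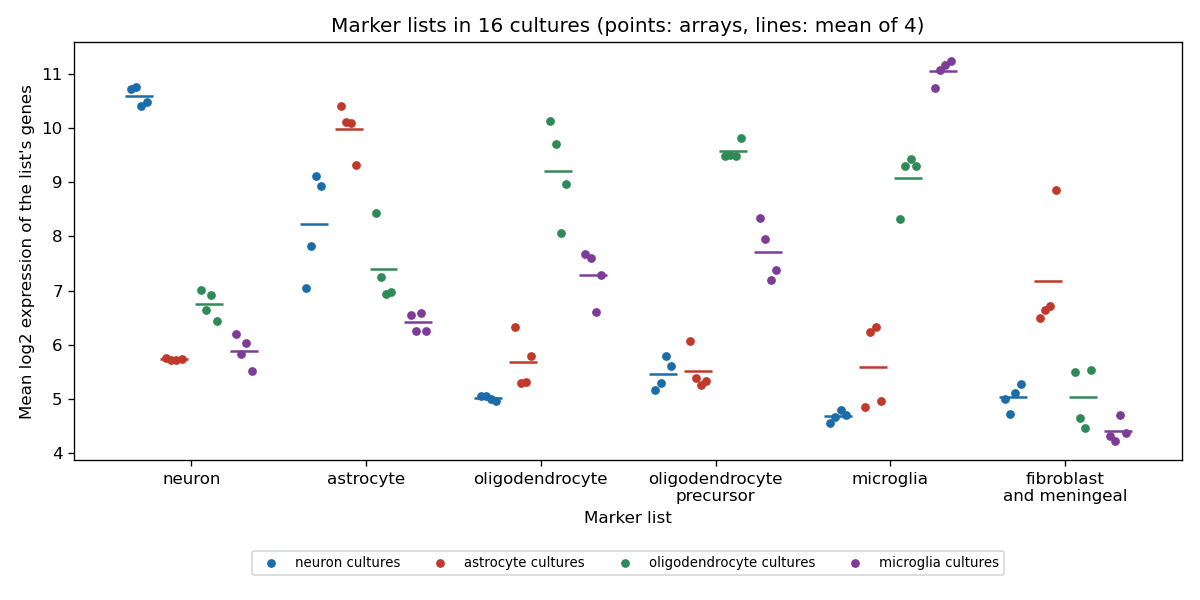
Mean log2 expression (vertical axis) of 6 marker lists (horizontal axis) on each of the 16 culture arrays, with the mean of 4 arrays as a line. The microglia list averaged 11.04 in microglial and 9.08 in oligodendrocyte cultures, and 1 astrocyte array, replicate 4, stood at 8.86 for the fibroblast and meningeal list.

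In astrocyte cultures the protease inhibitor A2m was at least 249-fold higher than in the mean of the other cultures (7.96 ± 0.38), at 13.03 ± 0.67 against 6.06 ± 1.17 in oligodendrocyte cultures, and the secreted serpin Serpinf1 was 173-fold higher (7.43 ± 0.32). The small leucine-rich proteoglycans Fmod (111-fold, 6.79 ± 0.20) and Omd (107-fold, 6.74 ± 0.11), the small heat shock protein Hspb1 (103-fold, 6.69 ± 0.49) and the actin-binding proteins Tagln (78.9-fold, 6.30 ± 0.52) and Cnn1 (68.4-fold, 6.10 ± 0.32) followed. Fibronectin, Fn1 (52-fold, 5.70 ± 0.35), Mfap4 (69.9-fold, 6.13 ± 0.39), Fbln2 (47.4-fold, 5.57 ± 0.50) and Efemp1 (39.7-fold, 5.31 ± 0.73) are matrix components, and Chrdl1 (55.8-fold, 5.80 ± 0.66) is an antagonist of bone morphogenetic proteins. Scn7a (62.7-fold, 5.97 ± 0.47), Ajuba (58.7-fold, 5.87 ± 0.21) and Cav2 (44.2-fold, 5.47 ± 0.35) completed the 15 genes that stood furthest above every other culture. Apart from Hspb1, Scn7a, Fn1, Fbln2 and Tagln, the other cultures averaged below the median of every array for these genes (10 of 15), so their folds are lower bounds. Efemp1 and Chrdl1 varied between astrocyte arrays (SD 2.82 and 2.53), and without astrocyte replicate 4 their differences were 6.72 ± 0.11 and 7.07 ± 0.10, with that of Mfap4 at 5.52 ± 0.27. For the 15 genes the limma adjusted p lay between 7.51e-15 and 2.88e-05. The rule required their lowest astrocyte array to exceed the highest array of every other culture. In all, 2528 probe sets were higher and 2345 lower, and 1306 (889 genes) were higher than in each other culture.

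Of the astrocyte list 11 of 15 genes were higher in astrocyte cultures (12 adjusted over the list alone, camera adjusted p = 0.000144, and adjusted p = 0.358 with an estimated correlation). These included the retinal dehydrogenase Aldh1a1 (6.06 ± 0.34), Aqp4 (5.15 ± 0.82), the gap junction protein Gja1 (4.62 ± 0.65), the growth factor receptor Fgfr3 (4.58 ± 0.32) and Gfap (3.30 ± 0.55). The glutamate transporter Slc1a2 stood at 4.65 ± 0.23 and Gjb6 at 3.29 ± 0.09, near the floor of the arrays in every culture. Neural progenitor genes were higher for 7 of 8 (7 adjusted over the list alone, camera adjusted p = 5.56e-05, and adjusted p = 0.04 with an estimated correlation). These included the cortical transcription factors Pax6 (4.38 ± 0.21) and Emx2 (3.51 ± 0.17) and the filament Nes (2.81 ± 0.21). The reactive astrocyte list had 7 of 10 higher (7 adjusted over the list alone, camera adjusted p = 0.000482, and adjusted p = 0.246 with an estimated correlation). These included vimentin, Vim (3.03 ± 0.29), and the protease inhibitor Timp1 (3.86 ± 0.34). Ependymal genes were higher for 5 of 8 (5 adjusted over the list alone), among them the cilium gene Tekt1 (3.58 ± 0.34) and its regulator Foxj1 (2.43 ± 0.36), while the list itself did not pass (camera adjusted p = 0.0549, and adjusted p = 0.403 with an estimated correlation), except without astrocyte replicate 4 (adjusted p = 0.00843). The neuron list had 14 of 16 genes lower (15 adjusted over the list alone, camera adjusted p = 1.87e-06, and adjusted p = 0.0475 with an estimated correlation), and the microtubule regulator Stmn2 went the other way, at 3.43 ± 0.45 with a level of 11.47 ± 1.24 beside 3.61 ± 0.26 for Snap25 and 3.57 ± 0.10 for Dcx. Without astrocyte replicate 4 the differences were 5.76 ± 0.87 for Aqp4, 4.20 ± 0.14 for Tekt1, 3.08 ± 0.17 for Foxj1 and 4.04 ± 0.36 for Stmn2.

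The extracellular matrix list had 10 of 12 genes higher (10 adjusted over the list alone, camera adjusted p = 1.91e-05, and adjusted p = 0.221 with an estimated correlation). These included Sparc (4.58 ± 0.48), biglycan, Bgn (4.48 ± 0.41), and tenascin C, Tnc (4.57 ± 0.51). The fibroblast and meningeal list had 6 of 10 higher (6 adjusted over the list alone, camera adjusted p = 0.0085, and adjusted p = 0.144 with an estimated correlation). These included Ogn (5.30 ± 0.14) and the fibrillar collagen chains Col1a2 (4.21 ± 0.81) and Col3a1 (3.41 ± 0.81). The pericyte and smooth muscle list had 5 of 10 higher (5 adjusted over the list alone, camera adjusted p = 0.0178, and adjusted p = 0.291 with an estimated correlation). These included smooth muscle actin, Acta2 (3.44 ± 0.42). Astrocyte replicate 4 had the highest mean of the 3 lists, far from the others for the matrix and fibroblast lists but not for the pericyte and smooth muscle list (7.40 against 6.46 to 6.91). Col1a2 was 13.11 in replicate 4 and between 7.92 and 8.24 in the other 3, Col3a1 was 12.56 against 7.57 to 7.66, and Acta2 12.83 against 9.37 to 10.56. In the same replicate Gfap (12.04) and Aqp4 (9.97) were the lowest of the 4, and the astrocyte list averaged 9.31 against 10.08 to 10.41. Without replicate 4 the calls of the 3 lists and of the genes named here held, but the differences were 2.95 ± 0.55 for Col1a2, 2.17 ± 0.56 for Col3a1 and 2.77 ± 0.27 for Acta2.

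**Figure D2:**
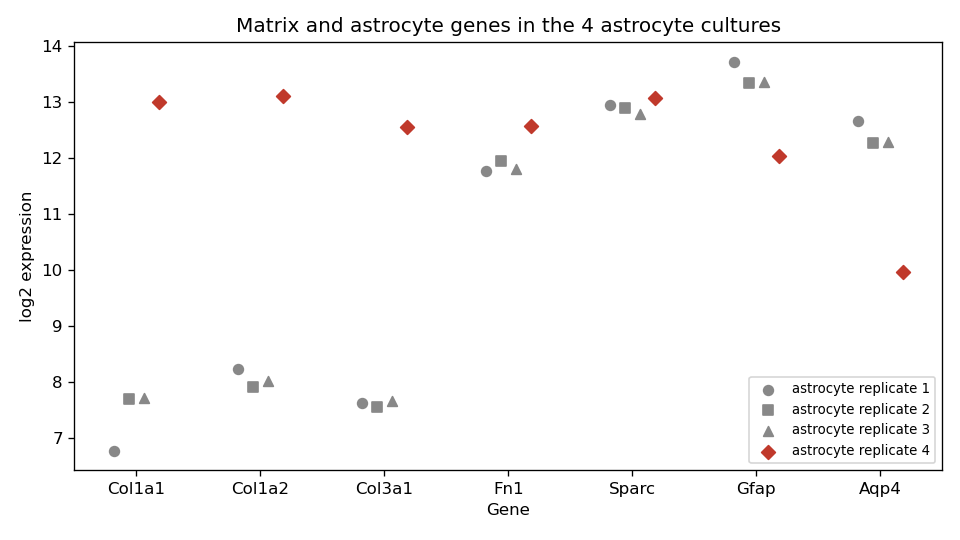
Log2 expression (vertical axis) of 5 matrix genes and 2 astrocyte genes (horizontal axis) on the 4 astrocyte culture arrays, 1 point per array. Replicate 4, in red, stood at 13.01 for Col1a1, where the other 3 lay between 6.78 and 7.72, and had the lowest Gfap and Aqp4.

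In oligodendrocyte cultures Ugt8, which makes the myelin lipid galactosylceramide, was at least 42.9-fold higher than in the mean of the other cultures (5.42 ± 0.44), and the lineage regulator Zfp488 was 31.9-fold higher (5.00 ± 0.32). The myelin transcription factor Myrf (25-fold, 4.64 ± 0.35), the fatty acid hydroxylase Fa2h (12.6-fold, 3.66 ± 0.15), the lysophosphatidic acid-producing enzyme Enpp2 (24.5-fold, 4.62 ± 0.46) and the receptor Lpar1 (21.3-fold, 4.41 ± 0.42) were also among the 15 genes furthest above each other culture. The others were Slco4a1 (20.1-fold, 4.33 ± 0.30), Lypd8l1 (20-fold, 4.32 ± 0.30), the cell cycle inhibitor Cdkn1c (18.5-fold, 4.21 ± 0.36), the proteoglycan-cleaving Adamts4 (17-fold, 4.09 ± 0.44), the collagen chain Col9a3 (16.1-fold, 4.01 ± 0.29), the phosphatase Dusp15 (15.9-fold, 3.99 ± 0.26), the interferon-induced protease Usp18 (15.7-fold, 3.97 ± 0.68), the semaphorin Sema5a (11.4-fold, 3.52 ± 0.29) and the transporter Abca8a (10.6-fold, 3.41 ± 0.36). For 7 of the 15, Ugt8 and Zfp488 among them, the other cultures averaged below the median of every array, so their folds are lower bounds. Microglial cultures came closest for 12 of these 15 genes, with Ugt8 at 7.07 ± 1.17 there against 10.29 ± 0.63. Zfp488 stood at 6.41 ± 1.17 there against 9.76 ± 0.32. The limma adjusted p lay between 2.05e-09 and 0.000335. Each gene was higher on every oligodendrocyte array than on any other culture array, as the rule required. In all, 1676 probe sets were higher and 1430 lower, and 456 (277 genes) were higher than in each other culture.

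The oligodendrocyte list had 12 of 14 genes higher (12 adjusted over the list alone, camera adjusted p = 3.45e-09, and adjusted p = 0.117 with an estimated correlation). These included the myelin proteins Mbp (4.58 ± 0.70), Mag (4.93 ± 0.63), which was 5.75 ± 0.54 without oligodendrocyte replicate 3, and Cnp (3.58 ± 0.23). Opalin and Ermn, genes of mature oligodendrocytes, did not reach the log2 minimum of 1, with differences of 0.69 ± 0.22 and 0.34 ± 0.12 and levels of 4.53 ± 0.76 and 4.30 ± 0.39 in oligodendrocyte cultures. In the precursor list 9 of 11 were higher (9 adjusted over the list alone, camera adjusted p = 3.2e-08, and adjusted p = 0.0475 with an estimated correlation). These included Bcas1 (5.40 ± 0.47), the transcription factor Sox10 (4.46 ± 0.27) and the growth factor receptor Pdgfra (4.26 ± 0.26). Cholesterol synthesis genes were higher for 13 of 14 (13 adjusted over the list alone, camera adjusted p = 1.2e-10, and adjusted p = 0.132 with an estimated correlation). These included Idi1 (2.85 ± 0.28) and the lanosterol synthase Lss (2.08 ± 0.24). Cell division genes were higher for 9 of 16 (9 adjusted over the list alone, camera adjusted p = 8.36e-08, and adjusted p = 0.168 with an estimated correlation). These included Bub1 (1.45 ± 0.20). The same list was called higher in microglial cultures for 11 of 16 (11 adjusted over the list alone, camera adjusted p = 2.87e-06, and adjusted p = 0.208 with an estimated correlation) and in astrocyte cultures for 4 of 16 (4 adjusted over the list alone, camera adjusted p = 0.000711, and adjusted p = 0.358 with an estimated correlation), and each of these comparisons includes the neuronal cultures.

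In the same cultures the microglia list had 13 of 18 genes higher (13 adjusted over the list alone, camera adjusted p = 2.57e-07, and adjusted p = 0.208 with an estimated correlation). These included the immunoglobulin receptor chain Fcer1g (4.15 ± 0.36), Aif1 (4.04 ± 0.27) and the growth factor receptor Csf1r (2.61 ± 0.32). Its mean was 9.08 ± 0.52 against 11.04 ± 0.22 in microglial cultures, and oligodendrocyte replicate 1 had the lowest value, 8.31, below 9.29 to 9.43 on the other arrays. Inflammatory mediators were higher for 10 of 15 (10 adjusted over the list alone, camera adjusted p = 7.8e-06, and adjusted p = 0.193 with an estimated correlation), among them interleukin 1 beta, Il1b (5.22 ± 0.48), and the chemokine Ccl4 (3.93 ± 0.45). Il1b stood at 10.99 ± 1.39 there, with a difference of 4.61 ± 0.42 without oligodendrocyte replicate 3, and at 8.53 ± 1.15 in microglial cultures. Interferon-stimulated genes were higher for 8 of 11 (9 adjusted over the list alone, camera adjusted p = 0.00102, and adjusted p = 0.409 with an estimated correlation). These included Mx2 (3.31 ± 0.52) and Oas1a (2.80 ± 0.56), and the mean of that list ran from 6.77 in oligodendrocyte replicate 1 to 9.48 in replicate 3. Other immune lists were not called there: MHC class I and peptide loading had 1 of 9 higher (camera adjusted p = 0.155, and adjusted p = 0.687 with an estimated correlation), and complement other than C1q 3 of 7 higher and 1 lower (camera adjusted p = 0.491, and adjusted p = 0.687 with an estimated correlation). MHC class II genes did not pass as a list either (camera adjusted p = 0.858, and adjusted p = 0.932 with an estimated correlation).

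In microglial cultures the complement protease Cfd was at least 57.5-fold higher than in the mean of the other cultures (5.85 ± 0.29), the scavenger receptor Stab1 52.2-fold (5.71 ± 0.26), the nucleotide receptor P2ry12 at least 47.7-fold (5.58 ± 0.19) and the lysophospholipid receptor Gpr34 at least 44.3-fold (5.47 ± 0.18). The lipid receptor Trem2 (36-fold, 5.17 ± 0.22), the growth factor Igf1 (24.7-fold, 4.63 ± 0.74), the myeloid transcription factor Cebpa (17.2-fold, 4.11 ± 0.14), the lectin Fcna (22.1-fold, 4.46 ± 0.14) and urokinase, Plau (18.2-fold, 4.19 ± 0.32), were also among the 15 genes furthest above each other culture. Rasgrp3 (32.5-fold, 5.02 ± 0.32), Tbc1d4 (31.2-fold, 4.96 ± 0.16), Slco2b1 (20.8-fold, 4.38 ± 0.20), Hcst (20-fold, 4.33 ± 0.20), C130050O18Rikl (19.2-fold, 4.26 ± 0.19) and Nrp1 (16.4-fold, 4.04 ± 0.33) completed them. Apart from Igf1, Trem2, Nrp1, Cebpa and Plau, the other cultures averaged below the median of every array for these genes (10 of 15), so their folds are lower bounds. P2ry12 stood at 9.83 ± 0.53 against 6.17 ± 0.42 in oligodendrocyte cultures, the next highest. Stab1 stood at 10.92 ± 0.15 against 7.48 ± 0.65 in oligodendrocyte cultures, also the next highest. The limma adjusted p lay between 1.03e-11 and 0.000107, with no overlap between microglial and other arrays, as the rule required. In all, 1956 probe sets were higher and 2778 lower, and 816 (546 genes) were higher than in each other culture.

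All 18 genes of the microglia list were higher (18 adjusted over the list alone, camera adjusted p = 3.12e-11, and adjusted p = 0.117 with an estimated correlation). These included Cd53 (5.80 ± 0.41) and complement C1qa (5.64 ± 0.60). Lysosome genes were higher for 11 of 12 (11 adjusted over the list alone, camera adjusted p = 3.2e-08, and adjusted p = 0.0728 with an estimated correlation). These included Ctsz (4.39 ± 0.30) and Gpnmb (3.27 ± 0.38). Of the MHC class II genes 3 of 8 were higher (3 adjusted over the list alone, camera adjusted p = 0.0199, and adjusted p = 0.276 with an estimated correlation), and these were the peptide-exchange chains RT1-DMa (2.69 ± 0.25) and RT1-DMb (3.97 ± 0.36) and the invariant chain Cd74 (1.04 ± 0.18), which stood at 5.01 ± 0.62 and fell below the log2 minimum without microglia replicate 2 (0.81) or replicate 3 (0.99). MHC class I and peptide loading genes were higher for 5 of 9 (5 adjusted over the list alone, camera adjusted p = 0.0197, and adjusted p = 0.509 with an estimated correlation). These included the immunoproteasome subunit Psmb8 (2.07 ± 0.30), and the list's camera adjusted p was 0.0534 without microglia replicate 4. Its mean was 8.40 in microglial, 8.31 in astrocyte, 8.01 in oligodendrocyte and 6.03 in neuronal cultures, so neurons stood apart more than microglia. Complement genes other than C1q split, with 4 of 7 higher, including the receptor C5ar1 (4.41 ± 0.31), and 2 lower, the proteases C1s (-4.19 ± 0.55) and C1r (-2.19 ± 0.34) (6 adjusted over the list alone, camera adjusted p = 0.345, and adjusted p = 0.576 with an estimated correlation). Cholesterol synthesis genes were lower for 13 of 14 (13 adjusted over the list alone, camera adjusted p = 5.94e-08, and adjusted p = 0.193 with an estimated correlation). These included the squalene synthase Fdft1 (-2.46 ± 0.16).

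Oligodendrocyte genes were measurable in microglial cultures. Myelin basic protein stood at 12.08 ± 0.74 there against 13.64 ± 0.86 in oligodendrocyte cultures, and Mbp (2.5 ± 0.70) was higher than in the mean of the other 3, as was the precursor gene Bcas1 (2.62 ± 0.47). Of the precursor list 4 of 11 were higher and 1 lower (6 adjusted over the list alone), and of the oligodendrocyte list 3 of 14 were higher (2 adjusted over the list alone), with neither list past the test (camera adjusted p = 0.176 and 0.312). The description of microglial replicate 4 reads as that of an RNA mixture while its title and cell type name a microglial culture. Its microglia list averaged 11.23, the highest of the 4 (10.74 to 11.15 in the others), and its neuron list 5.51, the lowest.

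Between pairs of cultures, neurons and microglia differed most, with 4378 probe sets higher and 3596 lower in neurons (7974 in all). Neurons and astrocytes differed for 7447 (3735 higher, 3712 lower) and neurons and oligodendrocytes for 6699 (3402 higher, 3297 lower). Astrocytes differed from microglia for 5023 (2835 higher, 2188 lower) and from oligodendrocytes for 4933 (2495 higher, 2438 lower). Oligodendrocyte and microglial cultures differed least, for 3277 probe sets (1946 higher and 1331 lower in oligodendrocytes). Of the 128 tests of 32 gene lists against 4 cultures, camera called 75, and 8 of these calls held with an estimated correlation. In neurons these were the neuron, synaptic vesicle, glutamate receptor and GABA-A receptor lists, all higher. In astrocytes the neural progenitor list was higher and the neuron and synaptic vesicle lists lower, and in oligodendrocytes the precursor list was higher. The lower calls in astrocytes mirror the neuronal ones, as the comparison includes neurons. The neuron list averaged 10.59 in neuronal, 5.74 in astrocyte, 5.90 in microglial and 6.75 in oligodendrocyte cultures. Of 158 other probe sets for list members, 40 differed from the chosen one in being called or not in neurons, 48 in astrocytes, 37 in oligodendrocytes and 39 in microglia. In astrocytes 1, for the glutamate transporter Slc1a3, was called in the opposite direction, so the call of that gene depends on the probe set.

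The neuron-astrocyte mixtures ask how expression follows a known share of neuronal RNA. The slope on that share is given per unit of neuronal fraction, over the 6 mixtures, with its standard error. Rasgef1a, a Ras exchange factor, had a slope of 3.29 ± 0.25 and rose from 6.78 in NA1 to 8.42 in NA3. Among the genes picked by the fixed rule, positive slopes also belonged to Plcxd3 (3.69 ± 0.49), the epilepsy-linked secreted protein Lgi1 (3.65 ± 0.49), Cpne4 (3.59 ± 0.46), the transcription factor Pou3f1 (3.48 ± 0.38), Coch (3.42 ± 0.42), Ptprr (3.35 ± 0.71) and Bend5 (3.30 ± 0.36). Negative slopes belonged to the endocytic protein Ehd2 (-4.12 ± 0.72), Fam111a (-4.04 ± 0.58), Ppic (-3.96 ± 0.93), the cholesterol acyltransferase Soat1 (-3.93 ± 0.55), Cfap100 (-3.91 ± 0.70), the cytokinesis factor Ect2 (-3.91 ± 0.60), and the matrix genes Ogn (-3.86 ± 0.70) and Fbln1 (-3.86 ± 0.38). Their limma adjusted p lay between 0.00404 and 0.0369, and the mean moved in 1 direction from NA1 through NA2 to NA3 for each. All of these estimates were steeper than mixing at the stated fractions can give, even for a gene absent from 1 parent. The rule took the largest slopes, so their sizes overstate the effect of the neuronal share. In all, the slope was positive for 2892 and negative for 1555 probe sets (4447), of which 3892 were called in the same direction between neuron and astrocyte cultures, 555 were not called there and 0 went the other way, the mixtures being made from the same RNA. With the mixture number as a block the count was 7503 (3874 positive, 3629 negative). It was 2246 without NA3 replicate 2, and without both NA3 mixtures limma called 0, with 3260 at an unadjusted p under 0.05. Of 25 genes called and named for the slope, 6 lost their call without NA3 replicate 1, 6 without NA3 replicate 2, 5 without NA1 replicate 2, 3 without NA2 replicate 1, 2 without NA1 replicate 1 and 1 without NA2 replicate 2.

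The neuron list had 14 of 16 genes with a positive slope (15 adjusted over the list alone), such as Rbfox3 (2.81 ± 0.29) and Snap25 (2.08 ± 0.26), and the synaptic vesicle list 9 of 13 (10 adjusted over the list alone). Cholesterol synthesis genes rose for 12 of 14 (14 adjusted over the list alone), including Hsd17b7 (2.61 ± 0.40) and Idi1 (2.15 ± 0.32). Cell division genes fell for 11 of 16 (14 adjusted over the list alone), including Cdk1 (-3.47 ± 0.45) and Mki67 (-3.42 ± 0.49), and neural progenitor genes for 4 of 8 (5 adjusted over the list alone), including Emx2 (-3.03 ± 0.22). In the astrocyte list only Aldh1a1 (-3.33 ± 0.70) and Glul (-1.99 ± 0.46) passed (2 adjusted over the list alone), and Gfap had a slope of -0.91 ± 1.55 and Aqp4 of -1.90 ± 2.47. The replicates of NA1 differed for these genes, with Aqp4 at 12.44 in replicate 1 and 9.73 in replicate 2, made from astrocyte replicate 4. The fibroblast and meningeal list had 3 of 10 genes with a negative slope (3 adjusted over the list alone), and Col1a1 stood at 5.82 and 12.72 in the NA1 replicates. With the mixture number as a block, which takes up such differences between parents, the astrocyte list had 9 of 15 negative slopes, Aqp4 among them (-1.90 ± 0.26, adjusted p = 0.00265), while Gfap did not pass (adjusted p = 0.0501). The blocked counts were 15 of 16 positive slopes for the neuron, 10 of 13 for the synaptic vesicle and 14 of 14 for the cholesterol synthesis list. Negative slopes numbered 15 of 16 for the cell division, 6 of 8 for the neural progenitor and 6 of 10 for the fibroblast and meningeal list. The slopes of Cdk1, Mki67 and Aldh1a1 were also steeper than mixing at the stated fractions can give.

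**Figure D3:**
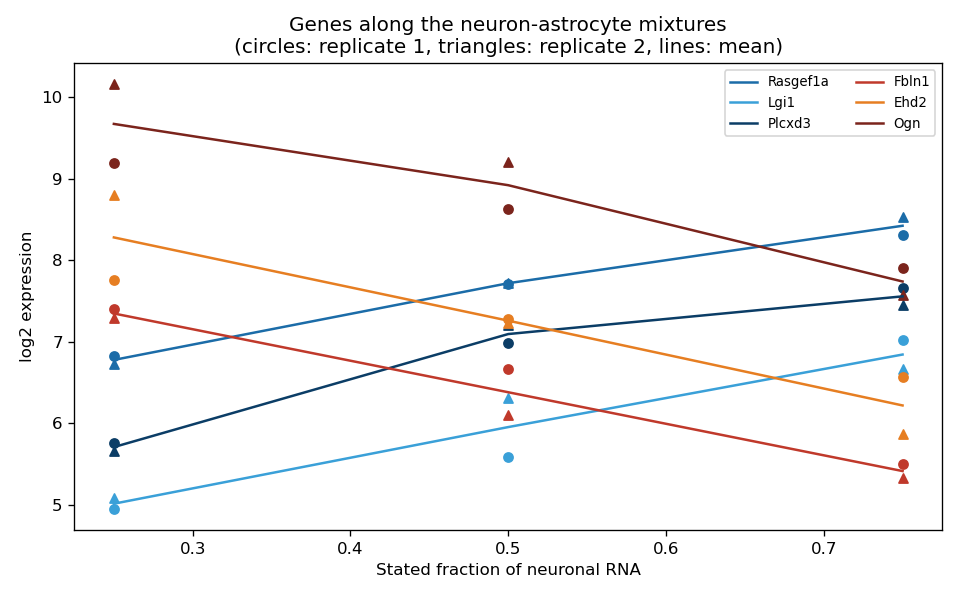
Log2 expression (vertical axis) of 6 genes against the stated fraction of neuronal RNA (horizontal axis) in the 6 neuron-astrocyte mixtures, with both replicates as points and their mean as a line. Rasgef1a rose from 6.78 to 8.42 and Fbln1 fell from 7.35 to 5.42 between fractions of 0.25 and 0.75.

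NAO against NA2 asks what replacing part of the astrocytic RNA by oligodendrocytic RNA adds at the same neuronal share (n = 2 arrays each). Adgre1, a macrophage surface receptor, rose by at least 6.67 ± 0.21, from 3.31 to 9.98, and stood at 11.63 ± 0.36 in the oligodendrocyte and 11.59 ± 0.71 in the microglial cultures. The immune genes Fcer1g (5.83 ± 0.20), Fcrl2 (5.60 ± 0.39) and lysozyme, Lyz2 (5.32 ± 0.29), and the lineage genes Bcas1 (5.83 ± 0.59) and Ugt8 (5.08 ± 0.44) followed, with Pnlip (5.41 ± 0.48) and Fxyd2 (5.07 ± 0.38). For Adgre1, Fcer1g, Fcrl2, Ugt8, Pnlip and Fxyd2 the NA2 level lay below the median of every array, so these differences are lower bounds. Genes that fell were Tc2n (-1.24 ± 0.19), Vstm4 (-1.22 ± 0.18), Casq1 (-1.22 ± 0.13), Ajuba (-1.20 ± 0.20), Omd (-1.05 ± 0.12), Rarres2 (-1.03 ± 0.17), Micall2 (-1.01 ± 0.14) and Zbtb20 (-1.0 ± 0.16). These falls lay at or past the largest that the lowered astrocytic share can give. The rule took the largest changes, so their sizes are overestimates. All 16 moved the same way in both mixture replicates, as the rule required, with a limma adjusted p between 4.47e-05 and 0.0424. The oligodendrocyte list rose for 6 of 14 (8 adjusted over the list alone), including Myrf (3.51 ± 0.11), and the precursor list for 7 of 11 (10 adjusted over the list alone), including Pdgfra (3.92 ± 0.15). The microglia list rose for 13 of 18 (16 adjusted over the list alone), with Aif1 (4.93 ± 0.22) and Csf1r (3.52 ± 0.13), and the inflammatory mediators for 5 of 15 (6 adjusted over the list alone). In all, 280 probe sets were higher and 61 lower (341), of which 332 were called in the same direction between oligodendrocyte and astrocyte cultures and 0 in the other.

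The count of calls between NAO and NA2 depended on single arrays, with 113 and 115 without NA2 replicate 1 and 2, 175 and 145 without NAO replicate 1 and 2, and 66 with only these 4 arrays in the fit. With the mixture number as a block it was 1077 (575 higher, 502 lower), and 8 of 14 oligodendrocyte, 8 of 11 precursor, 16 of 18 microglia and 5 of 15 inflammatory mediator genes rose. Of 20 genes called and named for this comparison, 7 and 8 lost their call without NA2 replicate 1 and 2, 6 and 8 without NAO replicate 1 and 2, 4 without either NAOM replicate, 3 without either NA3 replicate and 2 without either NA1 replicate.

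NAOM against NAO asks what a microglial share of 0.1 adds, with the astrocytic and oligodendrocytic shares lowered. Cfd rose by at least 2.65 ± 0.23, from 4.56 to 7.20, and P2ry12 (2.18 ± 0.09) and Trem2 (2.11 ± 0.16) rose by more than 2 log2 units. Gpr34 (1.69 ± 0.12), cathepsin S, Ctss (1.65 ± 0.14), Nrros (1.63 ± 0.12), the sialic acid receptor Cd33 (1.56 ± 0.16) and Tbc1d4 (1.5 ± 0.12) followed. Each rose in both replicates, as the rule required (limma adjusted p between 0.00114 and 0.0485). Differences of Cfd, P2ry12, Gpr34 and Tbc1d4 are lower bounds, their NAO levels lying below the median of every array. The microglia list rose for 4 of 18 (13 adjusted over the list alone), and Fcer1g, already at 10.60 in NAO, differed by 0.82 ± 0.20 without passing. In all, 13 probe sets were higher, and all 13 were higher in microglial cultures than in the mean of the others. For genes that were lower limma called 0, out of 895 at an unadjusted p under 0.05 in both directions. Chance alone gives a share of about 0.05 of the 31042 probe sets tested. Both 895 and the 1211 given below for only these 4 arrays lie under that share. By themselves these counts therefore show no further changes. The astrocytic and oligodendrocytic shares were lowered only slightly, so mixing can give only small falls, and 0 lower calls says little. With the mixture number as a block 37 were called, 7 of 18 genes of the microglia list rose, and the count was 1 without NAO replicate 1 or without NAOM replicate 1, 3 without NAOM replicate 2, 7 without either NA3 replicate, 8 without the dimmest probe sets, 24 with a trended and robust variance and 0 with only these 4 arrays in the fit (1211 at an unadjusted p under 0.05). Of 8 genes called and named here, 7 and 6 lost their call without NAO replicate 1 and 2, 7 and 5 without NAOM replicate 1 and 2, 3 without either NA3 replicate, 2 without either NA2 replicate and 1 without either NA1 replicate.

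**Figure D4:**
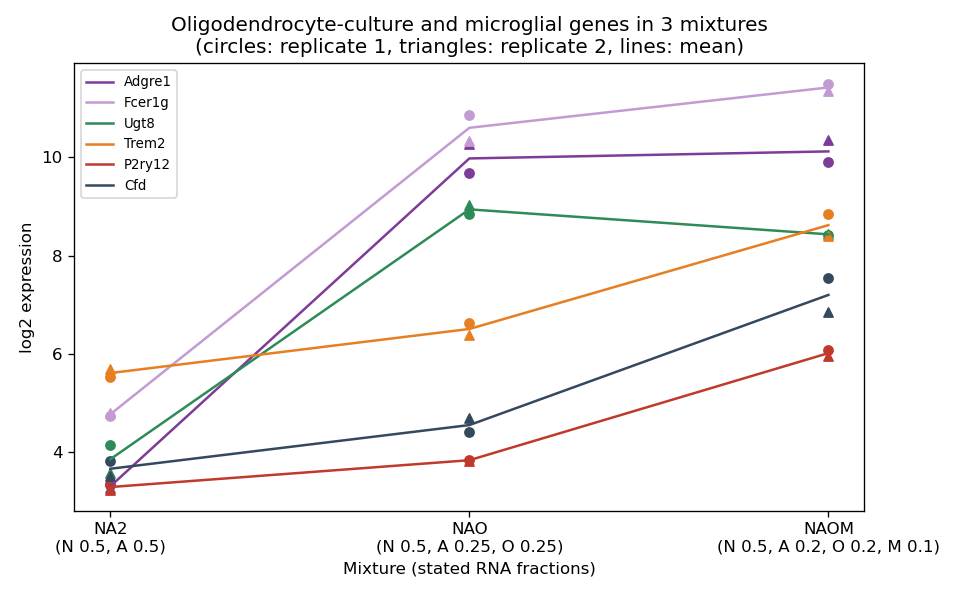
Log2 expression (vertical axis) of 6 genes in NA2, NAO and NAOM (horizontal axis, with the stated RNA fractions), both replicates as points and their mean as a line. Adgre1 rose from 3.31 to 9.98 between NA2 and NAO, and Cfd from 4.56 to 7.20 between NAO and NAOM.

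Each mixture was compared with the sum of its stated parents, weighted by their fractions on the linear scale. The root mean square deviation over 31042 probe sets lay between 0.23 and 0.29 log2 units across the 10 mixtures, within the range between replicate cultures (0.21 to 0.74). That range is a loose standard, since replicate cultures are separate cultures while each expected value comes from the RNA in the mixture. Its top came from astrocyte replicates 1 and 4. Between 99.2% and 99.9% of probe sets lay within 1 log2 unit of the expected value, and the median deviation lay between -0.15 and -0.08. Postn, a matrix gene, stood at 5.61 and 12.41 in the NA1 replicates, whose astrocytic parents stood at 3.90 and 12.47.

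RNA fractions estimated from the 63 genes of the neuron, astrocyte, oligodendrocyte and microglia lists differed from the stated ones by 0.0725 on average. The error was 0.125 for the neuronal, 0.141 for the astrocytic, 0.0171 for the oligodendrocytic and 0.0071 for the microglial share. The oligodendrocytic and microglial averages run mostly over mixtures with none of that RNA, where the fit is bounded at 0. They are therefore not comparable with the neuronal and astrocytic ones. The microglial share was estimated at 0.0696 and 0.106 in the NAOM replicates (stated 0.1) and 0 in NAO, and the oligodendrocytic share at 0.255 in NAO (stated 0.25) and 0.216 in NAOM (stated 0.2). The oligodendrocyte cultures used as reference held the microglia list at a mean of 9.08. The fit can therefore assign microglial transcripts in NAO to the oligodendrocytic share, and the 0 does not show that they were absent. In mixtures stated to hold neither, replicate 1 was given none. Replicate 2 was given oligodendrocytic shares of 0.0474 in NA1, 0.0262 in NA2 and 0.0351 in NA3, and microglial shares of 0.0174, 0.0136 and 0.0035. The neuronal share was higher than stated in each mixture on average, 0.342 in NA1, 0.611 in NA2 and 0.894 in NA3, and the astrocytic share lower. The replicates differed, with astrocytic shares of 0.146 and 0.0266 in NA3 (stated 0.25), 0.191 and 0.03 in NAO (stated 0.25) and 0.111 and 0 in NAOM (stated 0.2) for replicates 1 and 2. Replicate 1 of NA1 gave 0.265 neuronal and 0.735 astrocytic, and replicate 2, made from astrocyte replicate 4, gave 0.42 and 0.516. With the stated parents as reference the mean error was 0.0296, and with cultures that were not parents it was 0.112. With all probe sets it was 0.0449, and with the 4904 probe sets higher in 1 culture than in each other 0.0407. Neuronal parents (replicates 1 and 2) and the other neuronal cultures each formed a close pair. The contrast of 0.0296 and 0.112 therefore includes that split.

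**Figure D5:**
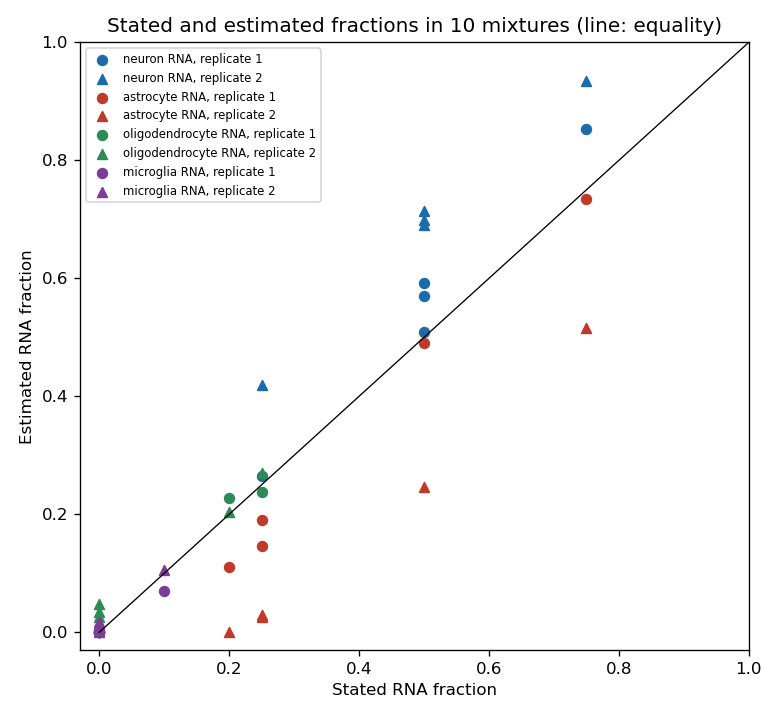
RNA fractions estimated from marker genes (vertical axis) against the stated fractions (horizontal axis) in the 10 mixtures, coloured by population, with equality as a line. Neuronal fractions of replicate 2, drawn as triangles, lay above the line, such as 0.42 for a stated 0.25.

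Expression of each population was also estimated by regression of the 10 mixtures on their stated fractions. The ratio of neuronal to astrocytic estimates gave the same results from the 6 neuron-astrocyte mixtures alone, so it rests on these. Estimates for oligodendrocytes and microglia were not assessed here. Over the 7447 probe sets called between neuron and astrocyte cultures, 6994 had a neuronal and an astrocytic estimate above 0. Spearman's rho of the log2 ratios across these, which are not independent replicates, was 0.9 against non-parent cultures and 0.968 against the parents. The contrast of parents and non-parents includes the split between the pairs of neuronal replicates. Without the replicate 1 mixtures rho against non-parent cultures was 0.82. These probe sets had been selected for a difference between the cultures. Over all 31042 probe sets rho was 0.778 and 0.858 (30564 with both estimates above 0), and the direction was the same for 74.8% and 77.9%.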

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

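The tests of exchanged RNA in NA3, of a single microglial share and of RNA quality in astrocyte replicate 4 were chosen after the values they measure had been seen, and the other tests before, though the meningeal list was written after the cultures had been seen. The mean of each gene list was compared between the 4 replicates of each culture. In 8 of 128 groups an array lay far from the other 3 relative to the range of the 4, where chance gives about 1 in 20, or 6.4. Of these, 4 were in astrocyte replicate 4. It had the highest mean of the fibroblast and meningeal list (8.86, others 6.493 to 6.715) and of the extracellular matrix list (11.21, others 8.781 to 9.047). Its endothelial (4.41, others 4.258 to 4.267) and voltage-gated channel (4.62, others 4.355 to 4.396) means were also the highest, but by little and near the floor. Astrocyte replicate 1 had the highest mean of the precursor list (6.07) and the lowest of the cell division list (7.53). Oligodendrocyte replicate 4 had the highest mean of the precursor list (9.81), and oligodendrocyte replicate 1 the lowest of the microglia list (8.31).

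Astrocyte replicate 4 held 213 probe sets at least 2 log2 units above each of the other 3, with a median of 2.96 above their mean, and Col1a1 at 13.01. Labelling or hybridisation of that array alone was argued against, because NA1 replicate 2, made from the same RNA, exceeded NA1 replicate 1 for 100% of them, by a median of 2.61 where 2.72 was expected. RNA quality as read by the 3' to 5' control ratio stays open. The log2 actin ratio of astrocyte replicate 4 was 2.00, against 1.11 to 1.61 in the other 3. Its Gapdh ratio was 0.58, against 0.16 to 0.29. In 4 of 5 mixtures replicate 2 had these probe sets higher and the actin ratio lower, such as 0.96 against 1.27 in NA1. In NA3 the actin ratio of replicate 2 was the higher, 2.31 against 1.17. These mixtures hold the RNA of astrocyte replicate 4 and differ in neuronal parent, so their ratios cannot decide the quality of that RNA. A test planned before, on oligodendrocyte replicate 2 with its similar ratio (median deviation -0.0913), decided nothing, as it rests on 1 array of another culture where these probe sets lay low (median 5.14). Damage that the ratio misses was not tested. Meningeal fibroblast-type cells may have contributed, but a second meningeal list had a median difference of 0.26, at percentile 98.1 of random lists, with only 2 of 14 genes (Twist1 at 2.00 and Bmp4 at 2.64) at least 1 higher, so this stays open. A different state of the astrocytes in that culture was not tested and stays open as well.

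Microglial genes were high in oligodendrocyte cultures and oligodendrocyte genes were measurable in microglial ones. A single share of microglia with the profile of the microglial cultures was argued against: over 18 genes the share needed ranged from 5.75% (Trem2) to 73.1% (Itgam), with a median of 26.1%, and its SD on the log2 scale was 2.17 times that between microglial replicates. Admixtures that differed between cultures could have contributed, since the SD of the microglia list mean over oligodendrocyte cultures, and of the oligodendrocyte list mean over microglial cultures, each lay at percentile 100 of random lists. The lists of each culture's own cells also lay at percentile 100, so the tests do not separate admixture from regulation. For the oligodendrocyte list in microglial cultures the median share was 15.8% (1.02% to 70.5%).

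The replicates of NA3 followed the neuronal parent of the other replicate number. Over 245 probe sets at least 1 log2 unit apart between neuron replicates 1 and 2, the difference of neuronal parent weights was -0.381 in NA3 and 0.49 to 1.16 in the other mixtures. An exchange of neuronal RNA stays open. With the neuronal parents crossed, the root mean square deviation over all probe sets fell from 0.267 to 0.234 in NA3 replicate 1 and from 0.277 to 0.241 in replicate 2, which goes with an exchange. Against it, on the 69 of the 245 probe sets unrelated to the 3' to 5' control ratio the difference of weights was 0.383 (bootstrap 95% interval 0.164 to 0.597), in the stated direction. That interval covers the choice of probe sets only and carries no error between arrays, so it excludes nothing by itself. An exchange of whole arrays was argued against by the weights of astrocyte replicate 1. With the stated parents these were 0.984 in NA3 replicate 1 and 0.0177 in NA3 replicate 2. With the neuronal parents of NA3 crossed, they differed by 0.876, also in the stated direction. RNA quality or labelling may have contributed: the log2 3' to 5' ratio of actin was 2.27 in neuron replicate 1 and 2.31 in NA3 replicate 2, against 1.17 in NA3 replicate 1. An exchange would put RNA of neuron replicate 1 into NA3 replicate 2, so these ratios do not separate quality or labelling from an exchange.

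For each culture comparison 1 of 100 regroupings of the 16 arrays, the real one, gave as many calls. The smallest share possible was 1 of 100, or 1 of 35 for pairs. Arrays mostly resembled each other more within than between cultures, so this outcome was largely fixed in advance. It cannot separate cell type from any preparation shared by the arrays of a culture. Against the mean of the others, neurons had 6984 calls and the highest other regrouping 3, astrocytes 4873 and 11, oligodendrocytes 3106 and 675, and microglia 4734 and 2543. For probe sets higher than in each other culture the values were 2326 and 0, 1306 and 0, 456 and 3, and 816 and 1, in the same order. The gene lists had 75 calls and the highest other regrouping 73, so the count of list calls by itself says little. For pairs of cultures, 1 of 35 splits gave as many calls: 7447 against a highest other of 0 for neurons and astrocytes, 6699 against 6 for neurons and oligodendrocytes, 7974 against 0 for neurons and microglia, 4933 against 134 for astrocytes and oligodendrocytes, 5023 against 148 for astrocytes and microglia and 3277 against 7 for oligodendrocytes and microglia.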

How the results depend on the processing

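The alternatives without NA3, with its numbers or parents crossed, with all probe sets for population expression, and without astrocyte replicate 4 for the lists and fractions were chosen after seeing the data, the others before. Over all counts and alternatives, 346 stayed within 1.5 times the reported count and 47 did not, and the cause was not tested except where fewer arrays or another fold minimum gives it by construction. Of list calls under the alternatives 301 of 375 held and 74 were lost, 6 tests gained a call and 259 had none either way, and none of the results run reversed. Leaving out 1 array, or blocking by replicate number, moved no culture count by more than 1.5 times: the counts ran from 6724 to 7170 for neurons, 4734 to 5130 for astrocytes, 2905 to 3230 for oligodendrocytes and 4512 to 4882 for microglia.

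With no fold minimum and with treat at a log2 difference of 1, the counts were 15186 and 4170 for neurons, 12750 and 2262 for astrocytes, 9551 and 739 for oligodendrocytes and 14031 and 2036 for microglia. For pairs they were 13747 and 4334 (neuron and astrocyte), 12826 and 3651 (neuron and oligodendrocyte), 15903 and 4949 (neuron and microglia), 10637 and 2125 (astrocyte and oligodendrocyte), 11928 and 2437 (astrocyte and microglia) and 8358 and 718 (oligodendrocyte and microglia). For probe sets higher than in each other culture they were 4146 and 1359, 2468 and 609, 1124 and 68, and 2361 and 270 in neurons, astrocytes, oligodendrocytes and microglia. List calls fell from 75 to 8 with an estimated correlation.

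The slope count was 7503 with a block, 4862 with the NA3 numbers crossed in it, 0 without NA3 (limma, 3260 at an unadjusted p under 0.05) and 2246 (without NA3 replicate 2) to 3385 without 1 array. NAO against NA2 gave 1077 with a block, 66 with only its 4 arrays and 113 to 324 without 1 array (113 and 115 without NA2 replicate 1 and 2, 175 and 145 without NAO replicate 1 and 2). NAOM against NAO gave 37 with a block, 24 with a trended and robust variance, 8 without the dimmest 25%, 0 with only its 4 arrays (limma, 1211 at an unadjusted p under 0.05) and 1 to 15 without 1 array (1 without NAO replicate 1 or NAOM replicate 1, 3 without NAOM replicate 2, 7 without either NA3 replicate). The deviation from expected mixtures, 0.262 as reported, was 0.336 with culture means, 0.399 with log2 mixing and 0.327 after median centring. The mean of its median deviations, -0.12 as reported, was -0.0584 with log2 mixing and -0.222 after median centring. The rho of population expression, 0.9 as reported, was 0.82 without replicate 1, 0.89 without replicate 2 and 0.778 with all probe sets. Signal near the floor of the arrays limits small differences in dim probe sets.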

Other observations

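The groups described here were on lists chosen before the data were examined, and no test was added for them. Of 12 glycolysis genes 4 were higher in neuronal cultures (4 adjusted over the list alone, camera adjusted p = 0.0288, and adjusted p = 0.36 with an estimated correlation). These included the phosphofructokinases Pfkm (2.27 ± 0.23) and Pfkp (2.25 ± 0.15) and the lactate dehydrogenase Ldhb (1.94 ± 0.29), while Ldha (-0.12 ± 0.18) did not pass. In microglial cultures 3 were lower (3 adjusted over the list alone, camera adjusted p = 0.0414, and adjusted p = 0.387 with an estimated correlation). These included Ldhb (-2.47 ± 0.29) and the hexokinase Hk1 (-1.99 ± 0.16). That adjusted p was 0.0569 without astrocyte replicate 4. Of 14 oxidative phosphorylation genes limma called 0 in neurons at the log2 minimum of 1 (12 at an unadjusted p under 0.05, 0 adjusted over the list alone), with a median of 0.43 and camera adjusted p = 0.00141, and adjusted p = 0.397 with an estimated correlation. Ribosomal protein genes were lower in neurons for 2 of 10 (2 adjusted over the list alone, camera adjusted p = 0.000234, and adjusted p = 0.305 with an estimated correlation), Rpl18 (-1.13 ± 0.09) and Rpl13a (-1.11 ± 0.09).

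Stress and early response genes differed gene by gene. Heme oxygenase, Hmox1, stood at 11.54 ± 0.19 in microglial and 6.98 ± 0.95 in neuronal cultures, and the growth arrest gene Gadd45a (2.98 ± 0.33) was higher in astrocyte cultures, but the heat shock and integrated stress list had 2 of 9 higher there (2 adjusted over the list alone, camera adjusted p = 0.0815, and adjusted p = 0.437 with an estimated correlation). Immediate early genes were lower in neurons for 4 of 11 (4 adjusted over the list alone, camera adjusted p = 0.449, and adjusted p = 0.758 with an estimated correlation). These included Atf3 (-2.52 ± 0.45), which was higher in microglial cultures at 2.64 ± 0.45. The phosphatase Dusp1 (2.70 ± 0.35) was higher in astrocyte cultures. Endothelial genes had 0 of 10 and erythroid genes 0 of 4 called by limma in neurons, with 7 and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.198 and 0.917), with the endothelial marker Cldn5 at 4.17 ± 0.49 in microglial cultures. The median, mean and test of a list differed in sign for 11 of 128 tests, 0 of them called.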
